A study of Danio rerio with 6 samples.

How the data were processed

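Gene expression was measured on one-colour arrays hybridised with biotin-labelled RNA from pooled telencephalons of male zebrafish. Per the labels, 3 arrays came from control fish and 3 from fish exposed to fadrozole, with about 30 telencephalons per array and no array left without a group. The scanner software, the scaling of the arrays and the probe-set summary are not given in the sources used here. Nothing in the labels says how far the pools of one group were independent of each other, so p-values measure the spread between these arrays.

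The deposited values are linear ratios: the median of the 3 control arrays equalled exactly 1 in all 15617 rows of the table, so each probe set had been divided by its control median before deposit. The ratios ran from 0.0177 to 106.7 with 0 values at zero. This division cancels in a difference between groups on the log2 scale, so fold changes are kept. The brightness of each probe set is lost, so dim and bright probe sets cannot be told apart, no filter on dim signals could be applied, and a large ratio may rest on a signal near background. The design fixed before the data were examined had assumed signal levels, and 4 of its steps, chosen for such levels, were replaced in the main setting: no offset of 16 was added before the log, arrays were not quantile normalised, the variance prior had no trend on mean level, and a gene with several probe sets was given their mean in place of its brightest probe set. Quantile normalisation and the variance trend can be run on ratios and were kept as alternatives, while the offset of 16, the brightest probe set and a filter on dim probe sets were not run.

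From the ratios, log2 values were computed and each array's shift was removed, taken as the median deviation of its probe sets from their means over the 6 arrays. The shifts were -0.11, 0.25 and -0.14 for control replicates 1, 2 and 3 and -0.07, 0.15 and -0.09 for fadrozole replicates 1, 2 and 3. The 115 control probe sets of the array maker were left out, which left 15502. GEO's platform annotation gave 1 gene symbol to 10795 of them, several to 135 and none to 4572, and none was named from a probe set with several. Of those with 1 symbol, 10711 were found by gene number in a RefSeq table for the GRCz12tu assembly, which was used for names only and updated 1 symbol. The named probe sets covered 8793 genes, 1539 of them with several probe sets.

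Fadrozole was compared with control by lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment. Counts of calls are over probe sets, and named genes and gene lists use the gene-level fit. A value after ± is the standard error of the log2 difference unless SD is written, and n is 3 arrays per group. Besides the adjusted p of 0.05, a count at unadjusted p under 0.05 with at least 1.5-fold change was fixed before the data were examined. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1.

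The named genes followed a rule fixed before the data were examined. It took cyp19a1b, cyp19a1a, esr1, esr2a, esr2b and ar, and 2 to 4 members with the smallest p for each gene list described. It also took the 10 genes higher and the 10 lower past the adjusted test. As none passed, places were filled by genes with unadjusted p under 0.05, at least 1.5-fold change and no overlap between the groups' arrays, in order of p. Clone-derived names were skipped, which passed over 0 genes among those higher and 1 among those lower before the 10th place. No probe set was named ar, and some lists described below have fewer named members than the rule sets.

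The 31 gene lists, also fixed in advance, were tested with camera of limma at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 31 lists. All had at least 5 measured genes. They covered steroid synthesis, steroid hormone receptors and partners, estrogen-induced genes, neuropeptides, GABA, glutamate and monoamine signalling, synaptic vesicles, the cell cycle, newborn neurons, immune response, immediate early genes, the circadian clock, heat shock, xenobiotic metabolism, cholesterol synthesis, ribosomal proteins, oxidative phosphorylation, the proteasome, genes of telencephalic regions and the olfactory system, radial glia, and 9 sets of markers for other cell types or tissues. Ribosomal proteins, oxidative phosphorylation and the proteasome were taken by symbol pattern. That for ribosomal proteins also matched 5 rps6k kinases, and that for the proteasome also matched psmc3ip. camera with a correlation estimated from the data and fry were run as alternatives. Where camera sets a list against the other genes, fry asks only whether the list itself changed, so their p-values answer different questions.

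The slide numbers in the labels fell into 2 runs, one holding replicates 1 and 3 of both groups (4 arrays) and one holding replicate 2 of both groups (2 arrays). Within each run the control slides had lower numbers than the fadrozole slides, so slide order cannot be told apart from treatment. Results are given also with the run as a block and within runs. Other alternatives were quantile normalisation, plain median centring, no shift removal, an added offset of 0.1, variance trends, array weights, other thresholds, the replicate number as a block, plain probe sets only, and leaving out each array in turn. The fit was tested on simulated data of 15502 probe sets with the spread of these arrays and 50 changed probe sets per size. The adjusted test recovered 0% at a log2 change of 1, 10% at 2, 46% at 3 and 78% at 4. The unadjusted test with the fold threshold recovered 46%, 84%, 96% and 100%. Of 15302 unchanged simulated probe sets, 5.10% had an unadjusted p under 0.05 and 6 passed the adjusted test.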

Results

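Transcripts were measured in the telencephalon, the front part of the forebrain, of sexually mature male zebrafish. Fish kept with fadrozole, a non-steroidal inhibitor of aromatase, at 200 µg/L for 10 days were compared with control fish. Aromatase converts androgens to estrogens, and the fish brain holds a form of its own, encoded by cyp19a1b. Each group had 3 arrays, each from a pool of about 30 telencephalons. The arrays gave ratios to the control median for 15502 probe sets, of which those with a single symbol stood for 8793 genes, and the number of arrays limits the precision. The comparison asks which telencephalic transcripts differ after aromatase inhibition in males.

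The transcript of brain aromatase, cyp19a1b, was 2.15-fold lower on the fadrozole arrays than on the control arrays (log2 difference -1.11 ± 0.31, n = 3 per group). As a set, genes of cholesterol synthesis lay higher than other genes, with 13 of 17 higher and a median log2 difference of 0.32. Immediate early genes lay lower, with 28 of 34 lower and a median of -0.28, and so did ribosomal proteins, with 73 of 78 lower and a median of -0.12. These 3 of the 31 lists passed camera, with adjusted p of 0.00949, 0.00949 and 0.0144. With an estimated correlation camera gave each an adjusted p of 0.978, from unadjusted p of 0.0813, 0.208 and 0.505. No single gene passed limma's adjusted test, so values of single genes below are measurements that did not pass it.

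Expression of cyp19a1b was -1.04 ± 0.40 (SD) on the fadrozole arrays and 0.07 ± 0.27 (SD) on the control arrays, as log2 level relative to the control median. In this mean of its probe sets all 3 fadrozole arrays lay below all 3 control arrays. The two-sided exact permutation p was 0.1, the smallest that 3 against 3 arrays allow. The limma fit gave an unadjusted p of 0.0118 and an adjusted p of 0.945 over 8793 genes. Between the array means the difference was -0.98 ± 0.22 within the larger slide run and -1.37 within the smaller one, and the limma fit of the larger run alone gave -0.99 ± 0.31 with an unadjusted p of 0.0377. Of the 3 probe sets of the gene, the one with the plain suffix _at differed by -2.01 ± 0.28, the one with the suffix _x_at by -1.13 ± 0.44 and the one with the suffix _a_at by -0.18 ± 0.41. The groups overlapped on both the _x_at and the _a_at probe set.

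**Figure D1:**
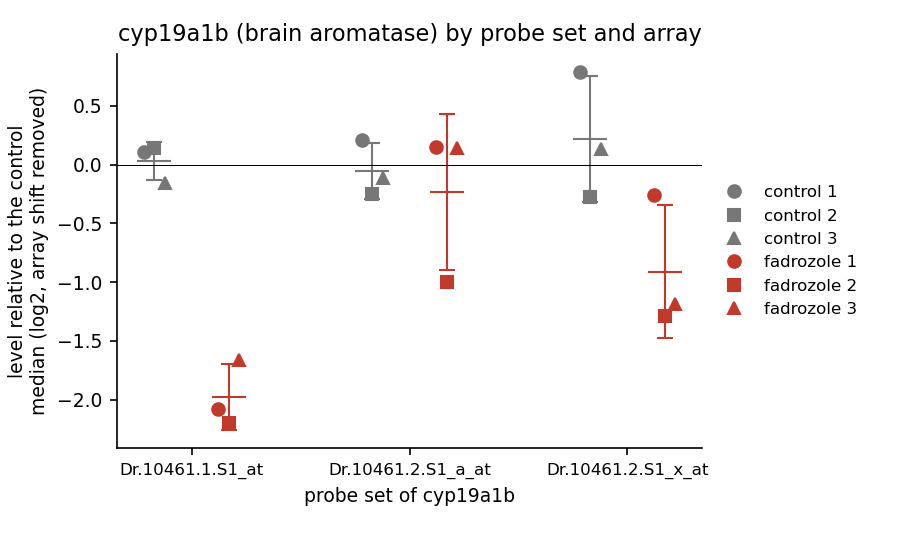
Log2 level of the 3 probe sets of cyp19a1b relative to the control median on the 3 control arrays (grey) and the 3 fadrozole arrays (red), with array shifts removed; each point is an array, and bars give the mean and SD. On the plain _at probe set the fadrozole arrays lie between -2.20 and -1.66, below all control arrays. On the _x_at and the _a_at probe sets the groups overlap.

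With all arrays, the other genes of estrogen signalling named in advance differed by less than 2 standard errors. Ovarian-type aromatase, cyp19a1a, was at 0.96 ± 0.57. The estrogen receptors esr1, esr2a and esr2b were at -0.55 ± 0.51, -0.66 ± 0.69 and -0.31 ± 0.43. With an array left out they ran from 0.43 (without fadrozole replicate 3) to 1.40 (without fadrozole replicate 1) for cyp19a1a and from -1.03 (without fadrozole replicate 1) to -0.20 (without fadrozole replicate 3) for esr1. For esr2a and esr2b they ran from -1.44 ± 0.30 and -0.74 ± 0.30 without control replicate 2 to -0.13 and -0.007 without control replicate 3. Within the larger and the smaller slide run, cyp19a1a was at 1.35 and 0.17, esr1 at -0.14 and -1.38, esr2a at -1.44 and 0.91, and esr2b at -0.85 and 0.77. Of the 10 measured genes that estrogen induces in fish, 7 were lower, with a median of -0.35 and a camera adjusted p of 0.184. Besides cyp19a1b, these included the egg yolk precursor vtg4 at -1.11 ± 0.76. The steroid synthesis list was split, with 13 of 25 genes higher, a median of 0.03 and an adjusted p of 0.923. In it, the androgen-producing enzyme cyp17a1 was at -0.87 ± 0.32 and the steroid reductase srd5a2a at 1.24 ± 0.47, with unadjusted p of 0.0335 and 0.0388 in limma. Of 21 steroid hormone receptors and partners, 12 were higher, with a median of 0.03 and an adjusted p of 0.923. The membrane progestin receptor paqr7b was at 0.63 ± 0.25. Both lists had a downward statistic in camera against an upward median, and the mean was 0.00995 for steroid synthesis and -0.000956 for the receptors.

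Genes of the cholesterol synthesis list had a mean log2 level of 0.42 ± 0.19 (SD) on the fadrozole arrays and -0.03 ± 0.32 (SD) on the control arrays. Their means on the 3 fadrozole arrays all lay above those on the 3 control arrays. Of the 31 lists, 2 had no overlap between the groups, this one and radial glia, where chance gives 3.1. The members with the smallest p were msmo1 and nsdhl, which act in sterol demethylation, at 1.23 ± 0.42 and 0.97 ± 0.35, the fatty acid desaturase scd at 0.74 ± 0.32, and hmgcs1, an early enzyme of the mevalonate pathway, at 1.33 ± 0.59. Only msmo1 and nsdhl of the 17 genes had an unadjusted p under 0.05 in limma, and 0 passed either over all genes or adjusted over the list alone. The list's median was 0.42 within the larger slide run and 0.37 within the smaller one, and camera with the run as a block gave an adjusted p of 0.0118. The call was lost without control replicate 1 (median 0.24, adjusted p = 0.176), without fadrozole replicate 2 (0.32, adjusted p = 0.382) in the larger slide run alone (0.42, adjusted p = 0.269), with an estimated correlation (adjusted p = 0.978) and with fry (adjusted p = 0.995).

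Immediate early genes had a mean log2 level of -0.13 ± 0.28 (SD) on the fadrozole arrays and 0.10 ± 0.12 (SD) on the control arrays, with overlap between single arrays. The members with the smallest p were klf2b at -2.36 ± 0.85, btg2 at -0.85 ± 0.36, egr2a at -0.59 ± 0.30 and cebpd at -1.09 ± 0.62. Only klf2b had an unadjusted p under 0.05 in limma, and 0 of the 34 genes passed over all genes or adjusted over the list alone. The median was -0.31 within the larger slide run and -0.32 within the smaller one, with an adjusted p of 0.00733 with the run as a block. The call was lost without control replicate 2 (median -0.22, adjusted p = 0.294), without fadrozole replicate 1 (-0.20, adjusted p = 0.545) and in the larger slide run alone (-0.32, adjusted p = 0.170). It was also lost with arrays centred on their plain median (median of the list -0.32, adjusted p = 0.0529) with no shift removed (-0.28, adjusted p = 0.0715), with an estimated correlation (adjusted p = 0.978) and with fry (adjusted p = 0.995).

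Ribosomal proteins differed little but mostly one way. Without the 5 rps6k kinases that the symbol pattern also took, 70 of 73 were lower, with a median of -0.12 and an adjusted p of 0.0203, but of 0.978 with an estimated correlation (0.476) and 0.995 with fry. The kinase rps6ka4, at -1.72 ± 0.63, had the smallest p of the list, followed by rpl21 at 0.70 ± 0.32. Of the 73 without the kinases, 0 had an unadjusted p under 0.05 in limma, and of all 78 genes 0 passed adjusted over the list alone. The median of the list was -0.04 within the larger slide run and -0.27 within the smaller one, with an adjusted p of 0.0118 with the run as a block. The call was lost without control replicate 2 (median -0.08, adjusted p = 0.251), without control replicate 3 (-0.10, adjusted p = 0.199), without fadrozole replicate 1 (-0.09, adjusted p = 0.341), without fadrozole replicate 2 (-0.06, adjusted p = 0.637) and in the larger slide run alone (-0.05, adjusted p = 0.805). It was also lost with plain median centring (-0.16, adjusted p = 0.0544), no shift removed (-0.12, adjusted p = 0.120) and array weights (-0.11, adjusted p = 0.0517), and for all 78 genes with an estimated correlation (0.428, adjusted p = 0.978) and fry (adjusted p = 0.995).

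**Figure D2:**
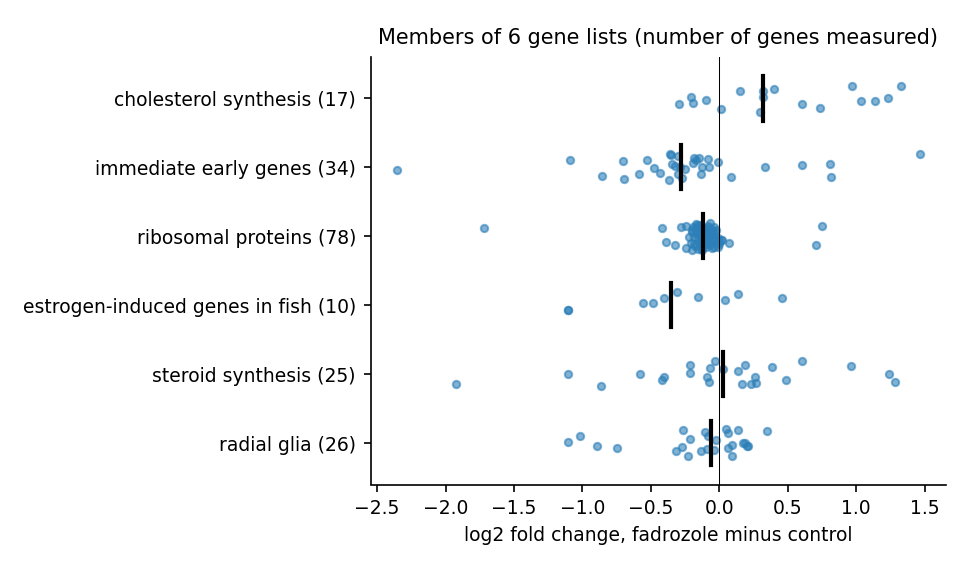
Log2 difference between fadrozole and control arrays for each measured member of 6 gene lists, with the number of genes in brackets; each point is a gene, spread vertically for legibility, and the black bar is the median of the list. The medians run from -0.35 for estrogen-induced genes to 0.32 for cholesterol synthesis.

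**Figure D3:**
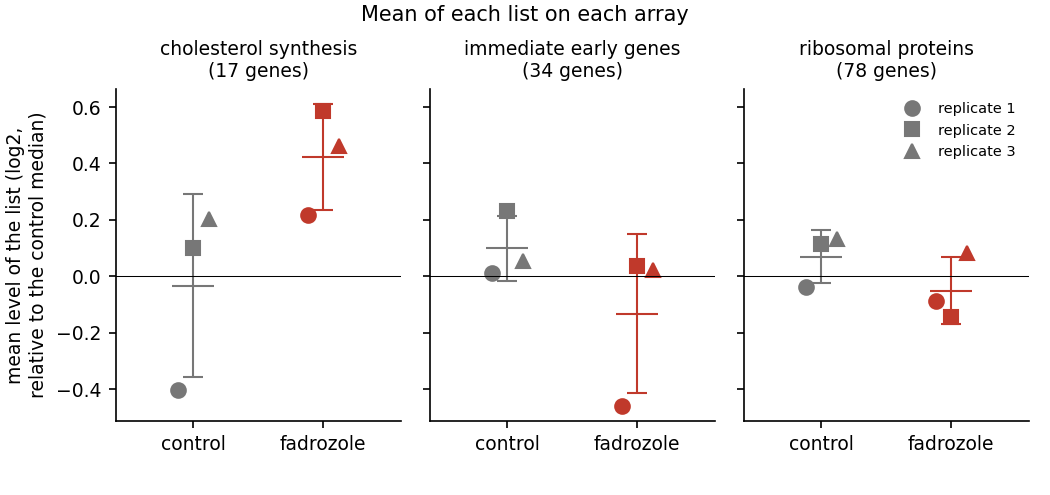
Mean log2 level of the 3 gene lists that passed camera on each array, relative to the control median, for control (grey) and fadrozole (red) arrays; bars give the mean and SD of 3 arrays. The fadrozole arrays lie above all control arrays for cholesterol synthesis and overlap with them for immediate early genes and ribosomal proteins.

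The 10 genes with the smallest p among those higher on all 3 fadrozole arrays had log2 differences from 1.47 to 2.92, each from 1 probe set. They were led by relt, a member of the tumour necrosis factor receptor family, at 2.68 ± 0.28, and by the transcription factor klf10, at 2.66 ± 0.41. The others were pih1d2, the prolyl isomerase fkbp9, ppp6r2a, the intestinal-type fatty acid binding protein fabp2, the fast muscle troponin tnni2a.3, the forebrain homeobox gene hesx1, irf2a and the syntaxin stx3b. The 10 lower genes ran from -3.13 to -1.53, also from 1 probe set each. They were led by haus5, a subunit of the augmin complex of the mitotic spindle, at -1.97 ± 0.24, the ciliary gene odad2 at -2.70 ± 0.34 and the homeobox gene hoxb5a at -2.57 ± 0.33. The others were terb1, btr02, dynlt5, the actin capping gene capgb, a2m3b, zdbf2 and the uridine kinase gene uckl1a. Adjusted p in limma ran from 0.471 to 0.703 over these 20 genes. In all, 156 genes were higher and 154 lower by the rule's thresholds, 18 and 19 of them with clone-derived names. Of all 8793 genes, 360 had an unadjusted p under 0.05 in limma, where chance gives 440.

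Among genes of nerve cell function, the 24 neuropeptide and hormone genes had a median of 0.02, with 14 higher. The tachykinin gene tac3b was at 0.69 ± 0.29 and gnrh3, which encodes a gonadotropin-releasing hormone, at 1.17 ± 0.56. In monoamine signalling 15 of 19 genes were lower, with a median of -0.32 and an adjusted p of 0.622, including ddc, an enzyme of dopamine and serotonin synthesis, at -1.04 ± 0.51, against adra2a at 1.33 ± 0.67. The 10 GABA genes had a median of -0.08, with gabarapl2 at -0.17 ± 0.26 and gabrb2a at 0.26 ± 0.44 (-0.15 without control replicate 3). The 14 glutamate genes had a median of 0.05, with the kainate receptor grik1a at 0.91 ± 0.49 and camk2d1 at -0.39 ± 0.30. Of 18 synaptic vesicle genes 9 were higher, including napab at 1.31 ± 0.35. For neuropeptides, GABA, glutamate and synaptic vesicles, camera's adjusted p was 0.889, 0.923, 0.889 and 0.971.

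Radial glia, the stem cells of the adult fish brain and the site of brain aromatase, had 15 of 26 genes lower, with a median of -0.06 and an adjusted p of 0.548. The mean of the list was -0.12 ± 0.07 (SD) on the fadrozole arrays and 0.03 ± 0.03 (SD) on the control arrays, with all 3 fadrozole arrays below all 3 control arrays. Besides cyp19a1b, the Notch target her4.2 was at -0.75 ± 0.24 and the receptor gene notch1a at -0.89 ± 0.35, with unadjusted p of 0.0223 and 0.042 in limma. The 51 cell cycle genes had 30 higher and a median of 0.11 (adjusted p 0.923). Among those with the smallest p, the replication licensing gene cdt1 was at -1.96 ± 0.53 and mcm7 at -0.64 ± 0.30. The 35 genes of newborn neurons had a median of 0.03 (adjusted p 0.889), with ncam1a at 1.25 ± 0.37 and the proneural gene neurog1 at 1.88 ± 0.62. Genes of telencephalic regions had 20 of 33 higher and a median of 0.14 (adjusted p 0.520), among them nkx2.1 at 0.64 ± 0.28 and pax6a at 0.65 ± 0.31. All 6 olfactory genes were higher, with a median of 0.32 (adjusted p 0.150), led by calb2b at 1.55 ± 0.69, followed by the olfactory marker gene ompb and by calb2a at 0.30 ± 0.30. Between same-numbered arrays the list's median was 1.80 for replicate 1, 0.20 for replicate 2 and -0.37 for replicate 3.

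The 9 sets of markers for other cell types or tissues had camera adjusted p from 0.889 to 0.923. Their medians were -0.04 for oligodendrocytes and myelin (16 genes), -0.14 for microglia and leukocytes (32), -0.04 for red blood cells (20), 0.02 for endothelium and pericytes (17), 0.08 for meninges and connective tissue (23), -0.06 for skeletal muscle (33), 0.36 for the pituitary (7), 0.04 for retina and lens (24) and -0.003 for other brain regions (39). For red blood cells the mean was 0.07 against a negative median and test statistic. Adjusted over the list alone, the myelin gene pmp22b passed at -1.28 ± 0.26 (limma, adjusted p = 0.0431) and hoxb5a, a hindbrain gene, passed in the list of other brain regions (adjusted p = 0.00911). These were the only members of any of the 31 lists to do so, and neither passed over all genes.

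Of stress, clock and metabolic genes, 25 of 46 genes of heat shock and the unfolded protein response were higher, with a median of 0.06, including the cochaperone bag2, 5.29-fold higher, and dnajb1a at 1.43 ± 0.49. Of 27 circadian clock genes 14 were lower, with a median of -0.06 and a mean of 0.02 and a downward test statistic, including the repressor ciarta at -1.75 ± 0.40 and nfil3-5 at 0.82 ± 0.25. Of 49 genes of xenobiotic metabolism 26 were higher, with a median of 0.03 against a mean of -0.08 and a downward test statistic. In limma 2 higher and 2 lower members had an unadjusted p under 0.05. Among the lower ones was cyp24a1, which breaks down vitamin D, at -1.29 ± 0.40. The 25 immune response genes had a median of -0.03, with isg15 at 1.24 ± 0.58 and saa at -1.82 ± 0.85. Oxidative phosphorylation had 45 of 78 genes lower and a median of -0.01, with uqcrc2a at -0.82 ± 0.31. The proteasome list had 36 of 50 higher and a median of 0.06, with psmb13a at -1.30 ± 0.86. Adjusted p was 0.889 for the last pair of lists and 0.923 for the other 4. With other scalings of the arrays the median of 23 of the 31 lists kept its sign. It turned under at least one scaling for steroid synthesis, steroid receptors, neuropeptides, newborn neurons, endothelium, retina, other brain regions and xenobiotic metabolism. For steroid synthesis, steroid receptors, neuropeptides and xenobiotic metabolism it turned only with plain median centring. That scaling put the median of all genes at -0.04.

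Across all probe sets, limma called 0 of 15502 at an adjusted p of 0.05, with a smallest adjusted p of 0.768. At an unadjusted p under 0.05 there were 655, where chance gives 775, and all 655 also changed at least 1.5-fold, 336 higher and 319 lower. With the slide run as a block these counts were 0 and 794, 426 higher and 368 lower, and without control replicate 2 the unadjusted count was 994. The groups did not overlap for 7.83% of probe sets, against 10% by chance. Across probe sets, which are not independent replicates, the log2 ratios of same-numbered fadrozole and control arrays correlated between replicates with r of 0.008, 0.031 and -0.010. For the 1539 genes with several probe sets, the differences of the first 2 correlated with r of 0.007 and had the same sign in 52.0%. The median standard error was 0.41 per gene. The correlations between replicates would also lie near 0 if few transcripts differed between the groups. By themselves they do not show poor data. Without signal levels it could not be checked whether weak signals or an error in the making of the deposited table lowered the agreement. Every fold change given here is subject to that doubt.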

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

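The test of the control probe sets was not among those planned before the data were examined. The array maker's 115 control probe sets, which the comparison of genes leaves out, held 4 that were higher on all 3 fadrozole arrays than on all 3 control arrays with an unadjusted p under 0.05 in limma. A control probe set for a zebrafish transcript whose gene the tables used here do not name differed by 3.12 on the log2 scale, at an adjusted p of 0.0388 over the 115, and was the only one past an adjusted p of 0.05. The probe set for the red fluorescent reporter AsRed2 differed by 1.43 (adjusted p 0.25). Probe sets for the synthetic tag sequences J and O differed by 1.8 and 1.74 (adjusted p 0.746 for each), while the probe sets for the other end of each tag differed by -0.41 and -0.43. In all, 6 of the 115 had an unadjusted p under 0.05, where chance gives 5.75. On the log2 scale, the median SD within groups was 1.25 for the 17 tag probe sets and 0.63 for the measured probe sets. It was 0.41 for the 18 hybridisation controls and 0.095 for the 3 control probe sets for GAPDH.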

How the results depend on the processing

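The alternatives without shift removal, with an offset of 0.1, with a variance trend alone, with plain probe sets only and without rps6k kinases (under each set test) were chosen after seeing the data. The count of 0 probe sets past the adjusted test held in all 19 alternatives, and that of 655 stayed within 1.5 times in 16. It was 154 at an unadjusted p under 0.01 and 338 with a robust variance trend, and ran from 646 to 994 when an array was left out, the highest without control replicate 2. cyp19a1b kept its direction and an unadjusted p under 0.05 in 16 of 17 alternatives, from -2.01 (plain probe sets only) to -0.88. The exception was the robust variance trend, with -1.11 and an unadjusted p of 0.0529 in limma; leaving out an array gave -1.26 to -0.88. The 3 gene lists became 1 with plain median centring, 1 with no shift removed, 0 in the larger slide run alone, 0 with an estimated correlation and 0 with fry. With an array left out they ran from 1 (without fadrozole replicate 2) to 4 (without fadrozole replicate 3). The cause was not tested. Cholesterol synthesis kept its call in 15 of 20 alternatives, immediate early genes in 13 and ribosomal proteins in 10, always in the same direction. Lists not called passed in single leave-outs: monoamine signalling (adjusted p 0.0383), immune response (0.0273), telencephalic regions (0.0295) and olfactory genes (0.00189). Of these 28 lists, 8 kept their camera direction in all 20 alternatives. No other named gene passed the adjusted test in any alternative. Of these, 20 were picked for arrays that do not overlap, so leaving one out cannot turn them. The arrays of cyp19a1b, as a mean of its probe sets, do not overlap either. Blocks and variance trends leave every log2 difference as it was, so they cannot turn a sign. cyp19a1a and the 3 estrogen receptors kept direction in all 67 values, and the 44 named list members, picked for small p, in 744 of 745. The exception was gabrb2a, -0.15 without control replicate 3 and 0.53 without control replicate 2. Same-numbered arrays correlated at 0.06, 0.19 and 0.09 in their deviations from the group means, so the numbers were not taken as pairs; each array correlated best with its own number, a hint from the data and not from the design. With a replicate block, the counts were 0 and 842 probe sets and 3 lists. The planned filter on dim probe sets, the offset of 16 and the brightest probe set per gene were not run, as they need signal levels.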

Other observations

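The radial glia test and both probe-set tests of cyp19a1b, its plain difference within the larger slide run and the within-run medians of cholesterol synthesis were chosen only after the result was seen. The limma fit of the larger slide run alone and that with an estimated correlation had been fixed in advance, but were set against these explanations after the result was seen.

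The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. For the adjusted test all 10 splits, the real one included, gave 0 probe sets, and the highest of the others was 0. For unadjusted p under 0.05 with 1.5-fold change, 6 of the 10 splits gave as many as the real 655, and the highest other gave 1188. For gene lists past camera, 5 of the 10 gave as many as the real 3, and the highest other gave 6. The 4 splits that put both replicate 2 arrays on the same side gave 884 to 1188 probe sets. The 6 that parted them, the real one included, gave 590 to 706, and the real one ranked 2 among them. The gap points to a structure that sets the replicate 2 arrays apart, by slide run or by pool number. With the run as a block, the real comparison gave 0 probe sets past the adjusted test and 794 at the unadjusted threshold.

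The lower cyp19a1b on the fadrozole arrays was weighed against 3 technical or compositional explanations. For the mean of the 3 probe sets, the plain difference within the larger slide run, which holds 4 arrays, was -0.98 ± 0.22. The limma fit of that run alone gave -0.99 ± 0.31 (unadjusted p = 0.0377). For this mean, these values argue against the smaller run as the only source. By probe set, the difference within the larger run was -1.85 for _at, -1.18 for _x_at and 0.10 for _a_at. The _a_at probe set was at -0.75 within the smaller run, so it was lower in that run only. A lower share of radial glia, the cells that make brain aromatase, would lower genes confined to these cells by about as much. Whether the other genes of the list are so confined was not tested. The median of the other 25 was -0.037 with a standard error of 0.085 over genes. Their mean was lower on all 3 fadrozole arrays than on all 3 control arrays, by a log2 difference of -0.11. A far smaller difference in radial glia is therefore not excluded. Nor is a larger one, because genes also made by other cells would fall less, dim probe sets could hide it and signal levels are lost. Whether the difference rests on 1 probe set is open, as the other 2 had a mean of -0.66 ± 0.38 (limma, unadjusted p = 0.135). The 3 probe sets differed in size, with a gap of -1.83 ± 0.35 between those with the suffixes _at and _a_at (limma, adjusted p = 0.00571 over the 3 pairs), so the 2.15-fold difference is a mean of unequal values.

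The replicate 2 arrays of both groups stood apart from the other 4. Set against them with treatment in the fit, they gave 1396 probe sets at an unadjusted p under 0.05 (9.01%) and 0 past limma's adjusted test. The next highest of the 9 pairs of a control and a fadrozole array, the replicate 3 pair, gave 1035. The 1396 may reflect a difference between slide runs. For replicate 2 the run and the number of the pool coincide, so neither can be separated from the other there. Replicates 1 and 3 share the larger run. Within it, deviations from the group means correlated at 0.06 and 0.09 for same-numbered arrays, against 0.03 and 0.02 for unlike numbers. No biological explanation was tested.

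The higher cholesterol synthesis genes were weighed against single arrays, the slide run and shared variation. Without any one array the median stayed at 0.24 or more, above its standard error over genes each time, which meets the bound set against a single array before the result was seen. That bound was too narrow, because it takes the genes as independent, and their estimated correlation was 0.0960. The error was widened for this only after the test had met the bound. The widened error was 0.34 against a median of 0.32 without fadrozole replicate 2, so a single array stays open, and the call was lost without that array or control replicate 1. Each slide run holds both groups equally, so a shift shared by a whole run cancels in the comparison by design. An effect of slide order within a run does not cancel, because control slides had the lower numbers in each run. Whether 1 run alone carries the pattern stays open. The median was 0.42 within the larger run, about equal to its widened error of 0.42, and 0.37 within the smaller one, which has 1 array per group and so no spread between arrays. Genes of the list varying together between arrays also stays open, since the adjusted p was 0.978 with an estimated correlation. An effect of fadrozole on sterol synthesis may be worth testing with more pools, and these data do not settle it.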
